A study of Mus musculus with 10 samples.

How the data were processed

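Lung cell suspensions came from C57BL/6J mice, an inbred laboratory strain, after 12.5 Gy of γ-radiation to the thorax or, in age-matched controls, 0 Gy. Pools were taken at 24 hours and at 1, 4, 12 and 32 weeks. Per the labels' protocols, each of the 10 libraries holds RNA of 3 mice, and the kits were Qiagen RNeasy PLUS, Clontech ultralow and Illumina NexteraXT. The NexteraXT chemistry does not mark the strand, so fragments of a gene and of an overlapping antisense gene cannot be told apart. The labels name no molecular identifiers, so PCR copies count as fragments. Each time and treatment had 1 pool, and the labels pair each irradiated pool with a control pool of the same time.

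Per the submitters' processing notes, Trimmomatic 0.32, STAR 2.4.2a, Cufflinks 2.0.2 and Cuffdiff were used with mouse build GRCm38.p4. The version of Cuffdiff, the role of each tool and the gene annotation are not given in the sources used here. The authors deposited expected counts (estimated fragments per gene) and FPKM values (fragments scaled by gene length and library total) for 45786 genes. In the deposited expected counts, low values of a library lay at multiples of a step that differed between libraries, from 0.58 to 1.38. Within a tolerance of 0.05, 76.3% to 82.0% of a library's values were whole multiples of it. The counts had thus been put on a scale common to the libraries before deposit. Deposited totals lay between 9983710 and 13509769, and division by the step gave 8679551 to 17473108 fragments. The authors' FPKM carry the same scaling, since the median ratio of count to FPKM lay between 0.977 and 1.007 of that in the 24-hour control. Table columns that belonged to no sample numbered 0, and 0 pairs of libraries were identical. Of the gene identifiers, 45137 were matched to GENCODE M21 for symbols and GRCm38 coordinates. The other 649 took at most 0.17% of the counts of any library.

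Expected counts were rounded to whole numbers and scaled by TMM, with factors from 0.933 to 1.086. Genes passing edgeR's filterByExpr with treatment as the group and a minimum count of 10 were tested, 15625 in all. Tests were 2-sided quasi-likelihood F tests (edgeR 4.0.16, robust, R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparison over the 5 times used time as a block and treatment, with 4 residual degrees of freedom and a common dispersion of 0.061. At each time the irradiated pool was set against the 5 controls, also with 4. That test takes the spread from controls of different ages and assumes that the lone pool varies like them. Its 5 controls span all times, so a difference in age between the pool and their mean is not told apart from irradiation. A change of the effect with time was tested as the product of treatment and log2 days (3 residual degrees of freedom), and a slope over log2 days in the controls with 6. All p-values measure the spread between pools, each 1 library, with biological and technical spread not separated. In the test over the 5 times, an effect of irradiation that differs between times also counts as spread. Fold changes against the matched control, at a prior count of 2, compare 1 pool with 1 pool and have no test. For a gene at 0 in a pool, a floor of 3 counts in that library gives the bound. Such floors cover counting error only, while the SE and SD values include the spread between pools.

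Gene lists covered p53 targets, DNA damage sensing and repair, cytokines and inflammatory mediators, interferon-stimulated genes, senescence, matrix and fibrosis, cell cycle, immediate early and heat shock, and circadian clock genes. Marker lists covered B, plasma, T and NK cells, alveolar macrophages, monocytes and interstitial macrophages, neutrophils, alveolar type 2 and type 1 cells, ciliated, club and secretory, endothelial, fibroblast, smooth muscle, mesothelial, cardiac muscle and red cells, thymocytes, and sex-linked genes. These 28 lists were tested with limma 3.58.1's camera on log2 CPM, at a preset inter-gene correlation of 0.01 and at an estimated one, and with fry, with adjustment over the lists of a comparison. The camera tests of the single times were also adjusted over the lists of all 5 times. The percentile of a list's median matched log2 fold was taken among 10000 random lists of the same size and mean expression, as a description. Another 7 lists were chosen after the data were seen and adjusted among themselves.

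The groups, the models, the 28 lists, the rule for named genes and most alternatives were fixed before the data were examined. Over the 5 times the rule names the 10 smallest p of each direction with 5 of 5 pairs alike when none passes, and always Cdkn1a, Mdm2, Ccng1, Cdkn2a, Tgfb1, Col1a1, Col3a1 and Ccl2. At each time it names the 5 largest rises and falls against the matched control among genes that pass. Where fewer than 5 of a direction pass, it takes genes of at least 50 counts on average that lie outside the range of the 5 controls. For changes with time it names the 10 smallest p, and from each list up to 4 members by p. Gene models without a common symbol and single immunoglobulin or T cell receptor segments were counted and not named. Some other genes that the rule names are not reported here.

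Alternatives were DESeq2 size factors, total count scaling, no filter, a filter of at least 5 CPM in at least 5 libraries, the Wald test of DESeq2 1.42.0, limma-trend on log2 FPKM with a pseudocount of 1 or 0.1, ranks of time, no time block, and leaving out each pool. Counts divided by their step, each control pool against the other 4, and camera at each time were added after seeing the data. The labels' age matching sets the pairing by time. The deviations of the pools of a time from their group means correlated across genes by 0.38, 0.07, 0.24, 0.06 and 0.16 in time order, and those of pools of different times by −0.28 to 0.23. The gene and list tests over the 5 times, at 24 hours, of the change with time and of the control slope were run on simulated data for the tested genes, with 100 genes changed 2-fold and 100 changed 4-fold. Tests at the other single times have the same form and were not simulated. The changed genes were drawn from those with at least 50 counts on average, and genes varied independently of each other. Over the 5 times each changed gene had the same fold in every pair. The shares called thus do not cover genes of few counts or of an effect that varies with time. Over the 5 times edgeR called 71 and 97 of the changed genes, with 8 false calls among 15376 genes, and at 24 hours 14 and 79, with 10 false calls among 15401. For the change with time it called 17 and 80, with 5 false calls among 15385 genes, and for the control slope 67 and 99, with 6 among 15381. DESeq2 made 26, 36, 35 and 27 false calls in the same 4 simulations. Genes with near-identical copies are uncertain, among them Ifit3, Oas1a, Ear1, the haemoglobin genes, the ribosomal protein genes with their pseudogenes, and immunoglobulin genes. Summaries and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.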

Results

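Transcript levels were measured by RNA sequencing in whole-lung cell suspensions of mice whose thorax had received 12.5 Gy of γ-radiation, and of age-matched mice that had received 0 Gy. The study followed DNA damage, inflammation, senescence and fibrosis genes from 24 hours through 1, 4, 12 and 32 weeks. There were 5 irradiated and 5 control libraries, each from a pool of 3 mice, with 1 pool for each time and treatment and so no replicate pool at any time. Before the authors' scaling, libraries held 14381209 ± 3358386 fragments in controls and 14417285 ± 1846619 in irradiated pools (SD, n = 5 each). The shallowest was the 12-week control with 8679551 and the deepest the 4-week irradiated pool with 17473108. On the first principal component, with 26.6% of the variance, the irradiated pools ran from −58.7 at 24 hours to 55.9 at 32 weeks. The controls ran from −24.7 at 24 hours to 19.6 at 32 weeks. Both groups rose in time order on it, so this component follows time in unirradiated lung too. Haemoglobin transcripts, a sign of blood in the suspension, took 0.80% to 6.67% of control counts and 2.1% to 6.57% of irradiated counts. Mitochondrial transcripts took 1.48% to 2.16% in controls, and in irradiated pools 1.72% at 24 hours and 1.15% to 1.28% later.

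Differences between pools with no irradiation set the background of every comparison. Each control pool against the other 4, in time order, gave 0, 0, 0, 1 and 0 genes with edgeR, the 1 gene being lower. It also gave 12, 9, 11, 8 and 11 of the 28 gene lists with camera at the preset correlation, and 0 each time with an estimated correlation. A list called at the preset correlation alone therefore does not set an irradiated pool apart from the differences between control pools.

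Across all times no single gene passed the test, which counts a change that differs between times as spread. Among the genes named by smallest p or in advance, C4b, Cdkn1a and Gdf15 lay higher in irradiated lung and Rpl12 lay lower. C4b, which encodes complement component 4 (ENSMUSG00000073418, GRCm38 chromosome 17, 34728380 to 34743882, minus strand), was at 404 ± 35.2 CPM (counts scaled to a common library total) in irradiated and 233 ± 22.6 CPM in control pools (SD, n = 5 each). It was higher in 5 of 5 pairs. Its log2 fold change was 0.79 ± 0.09 (SE; edgeR adjusted p = 0.15). Cdkn1a, which encodes the cell cycle inhibitor p21 (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727, plus strand), was 6.88, 3.77, 3.15, 2.27 and 1.21 times its matched control in time order (log2 1.57 ± 0.31, adjusted p = 0.169). Gdf15, a stress-induced cytokine (chromosome 8, 70629393 to 70632456), was at 15.3 ± 8.72 against 3.43 ± 1.94 CPM (log2 2.11 ± 0.35, adjusted p = 0.15). Rpl12, a protein of the large ribosomal subunit, was at 96.4 ± 13.8 against 149 ± 19.1 CPM and lower in 5 of 5 pairs (log2 −0.63 ± 0.09, adjusted p = 0.15).

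The other genes with the smallest p and 5 of 5 pairs alike did not pass either, each at an edgeR adjusted p of 0.15. Higher were the scavenger receptor gene Msr1 (log2 1.21), the coagulation factor gene F13a1 (0.83), Dab2 (0.65), Sdc3 (0.81), the calcium channel gene Trpv4 (1.497), the calcium pump gene Atp2a2 (0.61), the mesothelial gene Msln (0.66) and the lipoxygenase gene Alox15 (1.17). Lower were Rps15a (−0.71), Rpl37a (−0.66), Rps24 (−0.65), Rps12 (−0.72), Rps26 (−0.69), Rps4x (−0.52), Rpl37 (−0.55) and Tmsb10, which encodes an actin-binding thymosin (−0.55). Of the genes named for the study's themes, the p53 targets Mdm2 (0.55 ± 0.14 SE, adjusted p = 0.235) and Ccng1 (0.95 ± 0.20, adjusted p = 0.183) and the monocyte attractant Ccl2 (0.91 ± 0.47, adjusted p = 0.511) were higher in 5 of 5 pairs. Ccl2 was at 9.5, 1, 1.94, 1.38 and 1.02 times its matched control in time order, and its log2 change was 0.38 without the 24-hour pools. The fibrosis genes had small log2 changes that did not pass, Tgfb1 −0.22 ± 0.16 (adjusted p = 0.646, higher in 1 of 5 pairs), Col1a1 −0.18 ± 0.23 (0.811, 3 of 5) and Col3a1 −0.03 ± 0.16 (0.965, 2 of 5). The sign of Col1a1 turned without the 32-week pools (0.07), and that of Col3a1 without the 32-week pools (0.13), without the time block (0.02) and with limma on FPKM (0.10 and 0.11 at pseudocounts of 1 and 0.1). Fn1, which encodes fibronectin, was higher in 5 of 5 pairs (0.76 ± 0.14, adjusted p = 0.15). Cdkn2a, the senescence-associated p16 gene, had 0 fragments in 8 pools, 1 in the 32-week control and 6 in the 32-week irradiated pool, too few to test.

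With edgeR 0 genes passed over the 5 times (smallest adjusted p = 0.15), 1732 had an unadjusted p under 0.05, of which 1034 were higher, and DESeq2 called 153 higher and 105 lower. limma on FPKM called 0 with either pseudocount. A share of 12.48% of genes moved the same way in all 5 pairs, 1055 higher and 895 lower, against an average of 6.25% by chance. Genes vary together, and the spread of this share by chance was not computed, so it does not set irradiation apart from chance. Of the 28 lists, camera placed 8 higher and 7 lower. With an estimated correlation none of these 15 held, each at adjusted p = 0.582 with an estimated correlation, and fry called 0.

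Higher lists over the 5 times were the p53 targets (median log2 0.46, camera adjusted p = 5.1e-06), interferon-stimulated genes (0.68, with 22 of 22 members higher, adjusted p = 1.25e-07) and monocyte and interstitial macrophage markers (0.56, 1.24e-06). Also higher were cytokines (0.16, 0.0219), senescence genes (0.06, 0.0265), neutrophil (0.31, 0.0118), mesothelial (0.23, 0.0219) and red cell markers (0.57, 0.00431). Red cell medians against the matched control were 0.18, 0.07, 0.57, −0.14 and 1.79 in time order. The control of the last time had the lowest red cell level, at mean log2 CPM 6.82 against 8.473 to 10.505 in the other controls. The irradiated pool of that time, at 9.24, lay within the range of the controls. Adjusted over the list alone, 10 p53 targets, 4 interferon-stimulated genes, 9 monocyte and macrophage genes, 1 cytokine gene, 2 senescence genes, 1 neutrophil and 2 mesothelial genes passed, against 0 over all genes. Lower lists were T cell markers (−0.67, 17 of 17 lower, 8 when adjusted over the list alone, camera adjusted p = 6.7e-09) and cell cycle genes (−0.44, 2.08e-07). Also lower were B cell markers (−0.29, 0.000357), fibroblast markers (−0.39, 0.00302), NK cell markers (−0.15, 0.0219), DNA damage genes (−0.12, 0.0219) and thymocyte markers (0.0219). Examples are Eda2r, a p53-induced receptor gene (2.16 ± 0.38 SE, edgeR adjusted p = 0.15), Irf7, an interferon regulator (1.00 ± 0.29, 0.283), C1qb of complement (0.71 ± 0.15, 0.189) and Cd3d of the T cell receptor complex (−0.92 ± 0.17, 0.15). Matrix and fibrosis genes had 23 members higher and 24 lower, and 3 passed when adjusted over the list alone, with Fn1 and Itgav (0.45 ± 0.09, 0.181) lowest in p (camera adjusted p = 0.892). The lists of immediate early genes, circadian clock genes, plasma cells, alveolar macrophages, alveolar type 2 and type 1 cells, ciliated, club, endothelial, smooth muscle and cardiac muscle cells and the sex-linked gene Xist were not called either. Among them the test went against the sign of the median for immediate early genes (−0.02, test higher), alveolar macrophages (0.12, test lower) and cardiac muscle (0.03, test lower).

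**Figure D1:**
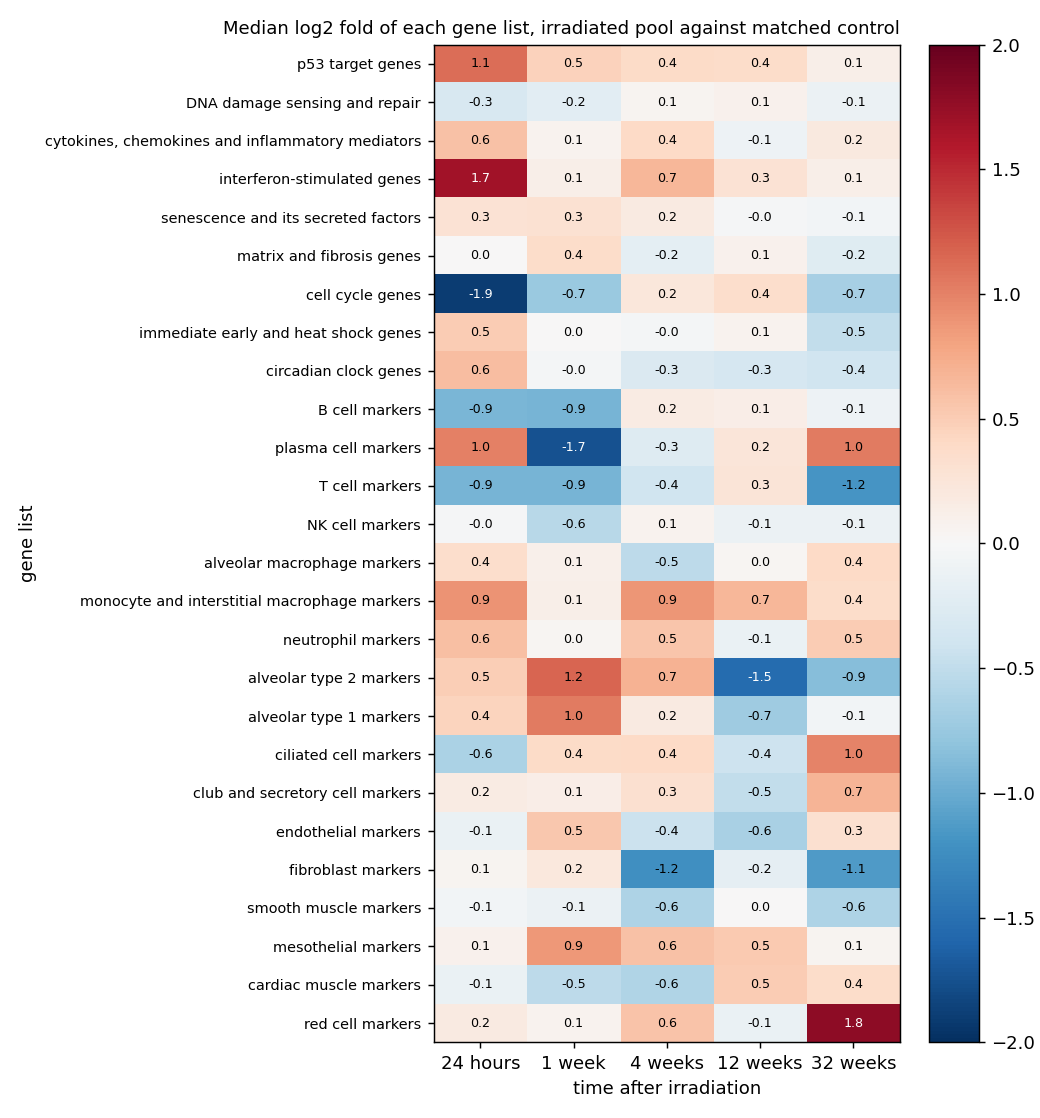
Median log2 fold of each gene list except thymocyte and sex-linked genes (vertical axis) in the irradiated pool against its matched control at each time (horizontal axis), red for higher and blue for lower, 1 pool against 1 pool with no replicate. Interferon-stimulated genes at 24 hours (1.68) and cell cycle genes at 24 hours (−1.89) lie far from 0, and alveolar type 2 markers go from 1.17 at 1 week to −1.54 at 12 weeks.

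At 24 hours 11 of 25 p53 targets and 14 of 22 interferon-stimulated genes rose, and 18 of 35 cell cycle genes fell. Cdkn1a rose to 517 CPM against 64.6 ± 11.02 CPM in the controls (SD, n = 5; log2 3.00 ± 0.20 SE, edgeR adjusted p = 0.000162). Ifit3, an interferon-induced antiviral gene (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731, plus strand), rose to 195 against 23.6 ± 2.47 CPM (adjusted p = 0.000113). It stood at 8.68 times its matched control. The chemokine genes Ccl2 and Ccl7 rose to 33.6 against 5.13 ± 1.19 CPM (adjusted p = 0.00559) and 53.03 against 6.01 ± 1.33 CPM (0.00132). Ccnb2, the cyclin B2 gene (ENSMUSG00000032218, chromosome 9, 70407692 to 70421547, minus strand), fell to 3.04 against 29.3 ± 4.26 CPM, 9.26-fold below its matched control (adjusted p = 0.00308).

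Of 25 p53 targets measured at 24 hours, 22 lay above the matched control (median log2 1.11), 11 rose in the test over all genes and 13 when adjusted over the list alone. Among them Phlda3, a p53-induced repressor of Akt (log2 2.19 ± 0.15 SE, edgeR adjusted p = 0.000248), Ccng1 (1.89 ± 0.19, 0.00221), the apoptosis gene Bax (1.42 ± 0.18, 0.00641) and Mdm2 (0.92 ± 0.17, 0.0403) rose. All 22 interferon-stimulated genes lay higher (median 1.68), 14 rose, and 21 when adjusted over the list alone, among them Ifit1 (2.55 ± 0.24, 0.0018), Irf7 (2.29 ± 0.23, 0.00221) and Oasl2 (2.34 ± 0.23, 0.00216). Both lists were called by camera (adjusted p = 3.67e-13 and 7.04e-25) and held when adjusted over the lists of that time, at adjusted p = 0.0155 and 0.0112 with an estimated correlation. Neither held when adjusted over the lists of all 5 times, at adjusted p = 0.0774 and 0.056 with an estimated correlation. Of 40 cytokine genes 5 rose, and 15 rose and 2 fell when adjusted over the list alone (1.53e-06; 0.169 with an estimated correlation). Ccl12 was among the 5 (2.16 ± 0.31, 0.0132). Saa3, an acute phase gene, rose to 309 against 20.7 ± 12.97 CPM (adjusted p = 0.0271). Of 30 senescence genes 4 rose, 5 when adjusted over the list alone (8.67e-06; adjusted p = 0.0439 with an estimated correlation, and 0.146 over the lists of all 5 times): Cdkn1a, Ccl2, Gdf15 (28.1 CPM, adjusted p = 0.0247) and Timp1, an inhibitor of matrix proteases (1.62 ± 0.31, 0.045). The largest rises against the matched control among passing genes were Saa3, Ces2e, a carboxylesterase gene (37.4 against 2.72 ± 1.49 CPM, adjusted p = 0.00509), Serpinb2, a plasminogen activator inhibitor gene (49.9 against 6.56 ± 3.32 CPM, 0.0187), Gdf15 and Ccl2.

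All 35 cell cycle genes lay lower at 24 hours (median log2 −1.89), 18 fell, and 33 when adjusted over the list alone (camera adjusted p = 6.68e-37; 0.0439 with an estimated correlation). Adjusted over the lists of all 5 times, the call was lost with an estimated correlation (adjusted p = 0.146). Ccna2 (−3.08 ± 0.33 SE, edgeR adjusted p = 0.00308), the spindle genes Tpx2 (−2.71 ± 0.30, 0.00308) and Nusap1 (−2.46 ± 0.30, 0.00604) and the mitotic kinase gene Pbk (−3.88 ± 0.54, 0.0115) fell. Fragments of Mybl2, a proliferation regulator, went from 81 in the matched control to 0, at least 24.1-fold lower. Sapcd2 went from 38 to 0 (at least 11.5-fold lower), Dscc1, a replication gene, from 35 to 0 (at least 10.4-fold) and Kntc1, a kinetochore gene, from 118 to 1. The repair genes Fancd2 (−4.08 ± 0.68, adjusted p = 0.0271) and Brca1 (−3.33 ± 0.62, 0.0403) fell, 2 of 31 DNA damage genes and 6 when adjusted over the list alone (camera 3.15e-06; 0.0786 with an estimated correlation). Of 19 B cell markers 6 fell, 16 when adjusted over the list alone (median −0.91, 4.42e-16; 0.2 with an estimated correlation), with Cd79a of the B cell receptor at 128 against 352 ± 53.8 CPM (adjusted p = 0.0271). Of 17 T cell markers 2 fell, Cd3d and Cd3g, and 15 when adjusted over the list alone (median −0.93, 1.49e-12; 0.265 with an estimated correlation). The thymocyte gene Rag1 went from 73 fragments to 0, at least 21.9-fold lower, and the list was called lower (0.00131; 0.315 with an estimated correlation).

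Lists of macrophages and epithelium were also called at 24 hours, none of them with an estimated correlation. Higher were monocyte and interstitial macrophage (median log2 0.90, camera adjusted p = 3.15e-06; 0.303 with an estimated correlation), alveolar macrophage (0.36, 3.39e-06; 0.35) and neutrophil markers (0.61, 0.000174; 0.308). So were alveolar type 2 (0.49, 7.06e-10; 0.308) and type 1 (0.45, 0.0109; 0.383) markers. Also higher were matrix (0.015, 0.000336; 0.315), mesothelial (0.09, 0.0161; 0.392) and circadian genes (0.62, 0.0484; 0.526). The circadian call was lost when adjusted over the lists of all 5 times (0.0687). The matrix median became negative with total count scaling. Camera compares with all 5 controls, and the 24-hour control had the highest matrix and mesothelial levels among them. Matrix genes were at mean log2 CPM 5.503 irradiated and 5.411 in that control, against 4.927 to 5.295 in the others. Mesothelial markers were at 4.476 and 4.451, against 3.287 to 3.737. Lower were ciliated cell markers (−0.63, 1.26e-06; 0.315 with an estimated correlation). Passing over all genes were 2 monocyte and macrophage genes and 9 adjusted over the list alone, 1 alveolar macrophage gene and 4, and 1 neutrophil gene and 4. Likewise passing were 2 alveolar type 2 genes and 14, 0 type 1 genes and 4, 2 matrix genes and 2, 0 circadian genes and 2 (1 higher and 1 lower), and 1 ciliated gene and 8. Ms4a7 (1.31 ± 0.23 SE, edgeR adjusted p = 0.0326), the scavenger receptor gene Marco (1.52 ± 0.26, 0.0301), Mmp9 (0.91 ± 0.18, 0.0464), the surfactant lipid transporter gene Abca3 (1.26 ± 0.19, 0.0171) and Etv5 (1.25 ± 0.21, 0.026) rose, and the dynein gene Dnah9 fell (−2.47 ± 0.48, 0.0464). Not called were plasma cell markers (median 1.00, test lower), NK cell (−0.03, test higher), club cell (0.16, test lower), endothelial (−0.14, test higher), fibroblast, smooth muscle (−0.05, test higher), cardiac and red cell markers, immediate early genes and Xist.

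In all 91 genes rose and 70 fell at 24 hours with edgeR, 54 and 64 with total count scaling, 199 and 325 with DESeq2, and 61 and 38 or 49 and 68 with limma on FPKM at pseudocounts of 1 or 0.1. Without the 1-week, 4-week or 32-week control the count of 161 became 61, 94 or 97, and without a filter 249. Calls depended on single controls, with the edgeR adjusted p without each in brackets, for Gdf15 (1-week 0.0675, 4-week 0.0503), Saa3 (24-hour 0.0982, 4-week 0.0725) and Serpinb2 (1-week 0.063). The same held for Cd79a (1-week 0.0737, 32-week 0.053), Cd3d (1-week 0.0574, 12-week 0.0849, 32-week 0.0809) and Cd3g (1-week 0.0845, 32-week 0.0739). Among the division and repair genes that fell, such calls were those of Fancd2 (1-week 0.0613, 4-week 0.0522, 32-week 0.0576), Mybl2 (1-week 0.0613, 4-week 0.054, 12-week 0.0559), Dscc1 (24-hour 0.0515, 1-week 0.0788, 4-week 0.0588, 12-week 0.0611) and Kntc1 (12-week 0.0577). Among cell type markers they were those of Abca3 (1-week 0.0554), Etv5 (1-week 0.0614), Marco (1-week 0.086, 12-week 0.0538, 32-week 0.0629), Ms4a7 (1-week 0.0825, 4-week 0.0562, 12-week 0.0538) and Dnah9 (1-week 0.0638, 4-week 0.0678, 12-week 0.0895, 32-week 0.0869). Leaving out any of the 5 controls, in time order, ended the calls of Brca1 (0.0558, 0.063, 0.0684, 0.0605, 0.0736), Timp1 (0.0704, 0.0973, 0.0796, 0.0577, 0.0577), Mmp9 (0.0808, 0.0613, 0.0723, 0.0886, 0.0858) and Sapcd2 (0.0704, 0.111, 0.0643, 0.0844, 0.0893). Over all alternatives of these genes the adjusted p ranged from 1.1e-07 to 0.396.

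**Figure D2:**
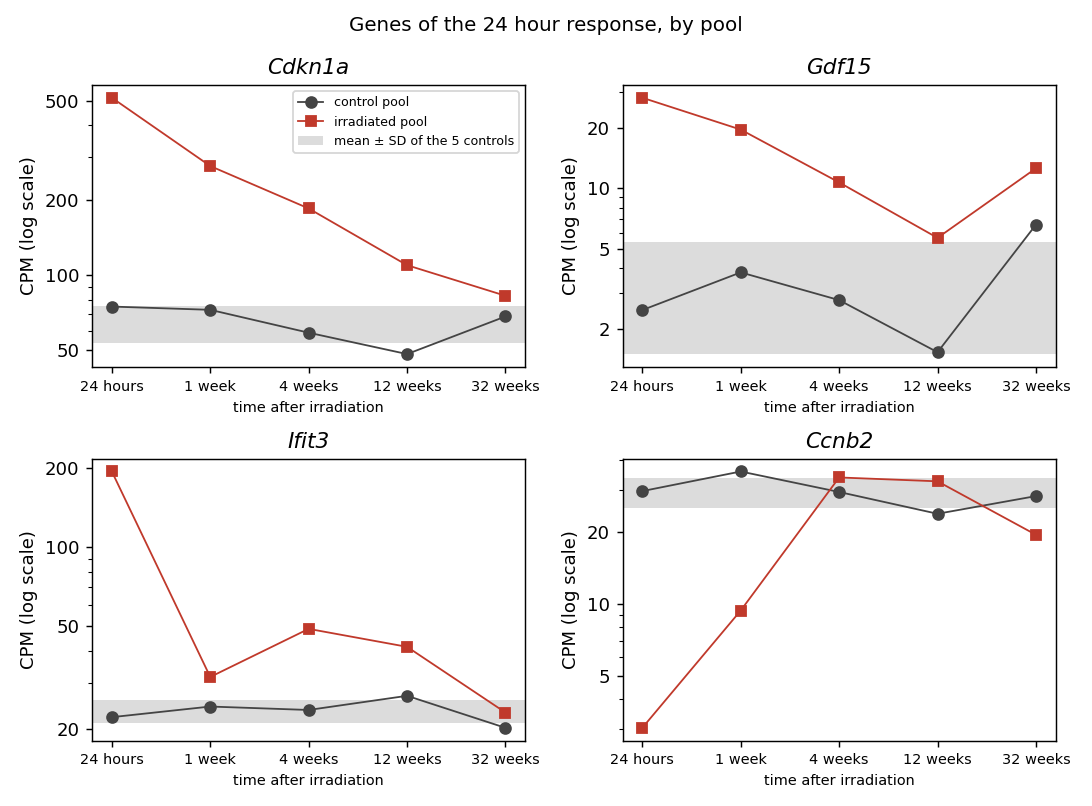
Abundance in CPM (log scale) of Cdkn1a, Gdf15, Ifit3 and Ccnb2 in each control pool (circles) and irradiated pool (squares) against time after irradiation, with the mean ± SD of the 5 controls shaded. Irradiated Cdkn1a goes from 517 at 24 hours to 275 at 1 week, and irradiated Ccnb2 is at 3.04 at 24 hours.

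At 1 week 3 genes rose, among them the p53 targets Cdkn1a and Phlda3. Cdkn1a rose to 275 CPM, 3.77 times its matched control (log2 2.09 ± 0.20 SE, edgeR adjusted p = 0.0211), and Phlda3 to 105 CPM, 3.18 times its matched control (1.52 ± 0.16, 0.0213). The third gene that rose was Ephx1, an epoxide hydrolase gene, at 344 against 138 ± 11.6 CPM in the controls (SD, n = 5; 0.0485), named after its values were seen. Of 25 p53 targets 21 lay higher (median 0.46), 2 rose, and 10 when adjusted over the list alone (camera adjusted p = 1.34e-06; 0.127 with an estimated correlation). Cell cycle genes had a median of −0.75 with 32 of 35 lower, 0 passing over all genes and 13 adjusted over the list alone (1.1e-15; 0.279 with an estimated correlation). Ccnb2 was 3.75-fold below its matched control.

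At 1 week B cell, T cell, plasma cell and thymocyte lists were called lower and alveolar type 2 and type 1 lists higher, none of them with an estimated correlation. B cell markers had 19 of 19 lower (median log2 −0.94, 0 passing and 7 adjusted over the list alone, camera adjusted p = 7.13e-10; 0.423 with an estimated correlation). T cell markers had 17 of 17 lower (−0.93, 0 and 2 adjusted over the list alone, 1.22e-09; 0.423 with an estimated correlation), and plasma cell markers 7 of 7 (−1.74, 0.00369; 0.474). Thymocyte markers were lower too, 3 of 4 (0.00305; 0.449), with Rag1 going from 66 fragments to 0, at least 17.4-fold lower. Rag2 went the other way, from 0 to 5 fragments, at least 2.22-fold higher by the same floor, though on few fragments. Also lower were DNA damage genes (−0.22, 0.00593; 0.423). Alveolar type 2 markers had 16 of 16 higher (1.17, 0 passing and 13 adjusted over the list alone, 8.25e-11; 0.423 with an estimated correlation) and type 1 markers 10 of 11 (1.04, 0 and 4, 0.00369; 0.449). Also higher were endothelial (0.54, 0.0042; 0.688), mesothelial (0.87, 0.011; 0.474), monocyte and interstitial macrophage (0.11, 0.00429; 0.474) and red cell markers (0.07, 0.0171; 0.671). Called higher as well were matrix genes (0.37, 35 of 47 higher, 0.000938; 0.449) and senescence genes (0.30, Cdkn1a alone passing and 2 adjusted over the list alone, 0.00787; 0.279). The other 13 lists were not called, among them NK cell markers (0.152), and for ciliated (0.366, test lower), club (0.0931, test lower) and smooth muscle markers (0.275, test higher) the test went against the sign of the median.

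Outside the range of the 5 controls but not passing at 1 week were, in CPM against the control mean ± SD, Eda2r (10.7 against 1.67 ± 0.70), Ces2e (16.9 against 2.72 ± 1.49), Tex15 (16.2 against 2.71 ± 1.25), Sel1l3 (10.1 against 2.04 ± 0.71) and Pde7b (8.05 against 2.04 ± 1.14). Lower were Cd207, the dendritic cell gene for langerin (0.75 against 15.1 ± 8.11), Itgae, an integrin gene of intraepithelial T cells and dendritic cells (12.2 against 57.4 ± 16.7), Sept3 (4.11 against 21.2 ± 5.003), Gcsam (2.35 against 13.01 ± 5.40) and Gpr141b (1.51 against 9.44 ± 3.46). Their edgeR adjusted p lay between 0.153 and 0.378. edgeR called 3 genes higher and 0 lower, with 1468 at an unadjusted p under 0.05, DESeq2 95 higher and 134 lower, and limma 2 with either pseudocount. The count became 0 with total count scaling and without the 1-week, 4-week or 32-week control, and 8 without the 12-week control. Cdkn1a then had adjusted p = 0.0971, 0.0711 and 0.0628 without the 1-week, 4-week and 32-week controls (range over its alternatives 1.67e-12 to 0.0971). Phlda3 had 0.0556, 0.102, 0.0719 and 0.0628 without the 24-hour, 1-week, 4-week and 32-week controls (1.44e-07 to 0.102).

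At 4 weeks 4 of 16 alveolar macrophage markers fell. Krt79, a keratin gene expressed by alveolar macrophages (ENSMUSG00000061397, chromosome 15, 101929332 to 101940324, minus strand), fell to 12.6 against 134 ± 23.3 CPM in the controls (SD, n = 5; log2 −3.41 ± 0.31 SE, edgeR adjusted p = 0.00351), 8.49-fold below its matched control. The eosinophil-associated ribonuclease gene Ear1 fell to 28.2 against 157 ± 23.1 CPM (adjusted p = 0.00905), the lectin gene Siglecf to 26.9 against 120 ± 18.9 CPM (0.0278) and the fatty acid binding gene Fabp1 to 11.2 against 81.6 ± 19.7 CPM (0.0278). Of 16 alveolar macrophage markers these 4 fell, and 11 when adjusted over the list alone (median −0.53, camera adjusted p = 4.65e-17; 0.398 with an estimated correlation). Cpne5, which encodes a calcium-dependent membrane-binding protein, fell to 6.06 against 45.6 ± 3.68 CPM (0.00351), and 1 gene without a symbol fell too (0.00351). Sowahc, an ankyrin repeat gene, rose to 16.9 against 1.51 ± 0.21 CPM (0.00905).

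Monocyte and interferon lists lay high at the same time. Interferon-stimulated genes had 20 of 22 higher (median log2 0.66, 0 passing and 8 adjusted over the list alone, camera adjusted p = 2.92e-08; 0.097 with an estimated correlation). Monocyte and interstitial macrophage markers had 12 of 13 higher (0.88, 0.00384; 0.584 with an estimated correlation), and p53 targets 18 of 25 (0.38, 0 passing, 8 higher and 1 lower adjusted over the list alone, 0.000179; 0.15). Alveolar type 2 (0.70, 2.57e-05; 0.584 with an estimated correlation), type 1 (0.19, 0.0169; 0.584), ciliated (0.39, 4.24e-05; 0.584) and club cell markers (0.32, 0.000143; 0.584) and cell cycle genes (0.23, 0.000699; 0.584) were called higher. Of these, 3 type 2 and 4 club cell genes passed when adjusted over the list alone and 0 over all genes. Camera compares with all 5 controls, and the 4-week control had the highest ciliated and club levels among them. Ciliated markers were at mean log2 CPM 6.4 irradiated and 6.089 in that control, and club markers at 8.259 and 7.886. Fibroblast markers (−1.23, 12 of 13 lower, 2.62e-05; 0.398 with an estimated correlation) and cardiac muscle markers (−0.61, 4.24e-05; 0.562) were called lower. Cytokine genes (0.40, 0.138, 3 higher and 3 lower when adjusted over the list alone) and neutrophil markers (0.55, 0.128, 4 higher when adjusted over the list alone) were not called. Of the other 15 lists none was called, and the test went against the sign of the median for B cell, red cell, thymocyte (−1.08, test higher), sex-linked and immediate early genes. Mmp12, a macrophage elastase gene, was at 318 against 59.6 ± 57.5 CPM and did not pass (edgeR adjusted p = 0.679). Nor did Zranb3 (24.0 against 4.55 ± 2.79 CPM, 0.394), Bicdl2 (7.21 against 1.93 ± 0.86 CPM, 0.475) or Il12b (11.2 against 5.75 ± 2.17 CPM, 0.785), each above all 5 controls.

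At 4 weeks edgeR called 1 gene higher and 6 lower, DESeq2 44 and 56, and limma 15 and 16 in all at pseudocounts of 1 and 0.1. The count of 7 became 4 without the 1-week control and 29 without a filter. Siglecf had edgeR adjusted p = 0.0618, 0.0873 and 0.081 without the 24-hour, 1-week and 12-week controls (range over its alternatives 3.33e-14 to 0.0873), Fabp1 0.126 and 0.101 without the 1-week and 32-week controls (1.04e-16 to 0.126) and Sowahc 0.0589 without the 1-week control (0.000727 to 0.0589).

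At 12 weeks markers of alveolar epithelium and endothelium lay low, and no gene passed. Sftpc, which encodes surfactant protein C of alveolar type 2 cells (ENSMUSG00000022097, chromosome 14, 70520949 to 70524081, minus strand), was at 4967 against 24140 ± 5542 CPM in the controls (SD, n = 5; edgeR adjusted p = 0.136), 5.42-fold below its matched control. All 16 alveolar type 2 markers lay lower (median log2 −1.54), 0 passing over all genes and 12 adjusted over the list alone (camera adjusted p = 4.28e-12; 0.804 with an estimated correlation), among them Sfta2 (−2.60 ± 0.44 SE, 0.136) and Cxcl15 (−1.68 ± 0.35, 0.188). Surfactant transcripts together took 0.68% of counts against 3.22% in the matched control. Of 22 endothelial markers 19 lay lower (−0.64, 9 when adjusted over the list alone, 3.79e-07; 0.913 with an estimated correlation), with Gpihbp1, the capillary anchor of lipoprotein lipase, at −2.12 ± 0.40 (0.162) and the angiopoietin receptor gene Tek at −1.81 ± 0.38 (0.188). Type 1 markers had 7 of 11 lower (−0.72, 4 when adjusted over the list alone, 0.0176; 0.913 with an estimated correlation), with Ager at −1.42 ± 0.31 (0.197).

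Also called at 12 weeks were monocyte and interstitial macrophage markers (median log2 0.66, 3 genes adjusted over the list alone, camera adjusted p = 0.000925; 0.913 with an estimated correlation), interferon-stimulated genes (0.29, 3, 0.000507; 0.416) and B cell markers (0.14, 2, 0.000215; 0.913), all higher, and circadian clock genes (−0.33, 1, 0.038; 0.913), lower. The 12-week control had the highest B cell level of the controls (mean log2 CPM 7.296, against 7.488 irradiated). Of the matrix genes 1 passed when adjusted over the list alone, Fn1, at 1076 against 532 ± 64.4 CPM (edgeR adjusted p = 0.162), and the list was not called (0.09, test lower, 0.548). The p53 targets were not called either (0.36, 4 higher and 1 lower adjusted over the list alone, 0.0978), with Cdkn1a at 110 CPM against 64.6 ± 11.02 (0.28). Nor were the other 19 lists, with the test against the sign of the median for several, such as T cell markers (0.25, test lower). Among them thymocyte markers had 4 of 4 higher (1.74, 0.548). Ccl8, a monocyte chemokine, was at 67.3 against 16.2 ± 3.86 CPM (0.136). The rule for single times named Myh7, a cardiac myosin gene, at 0.70 against 12.5 ± 1.89 CPM (0.065), with Pla2g1b (−2.90 ± 0.47 SE, 0.136), Slc38a4 (−3.05 ± 0.57, 0.162), Ppp1r9a (−3.03 ± 0.62, 0.188) and Cst8 (−2.62 ± 0.64, 0.23). Higher by the same rule were Naip1, with 97 fragments against 3 in the matched control, Pcsk1, with 103 against 1, Pdcd1 (1.15 ± 0.85, 0.653), Fancm (1.89 ± 0.65, 0.371) and Zfp169 (1.26 ± 0.65, 0.522). edgeR called 0 genes (smallest adjusted p = 0.065) with 1669 at an unadjusted p under 0.05. DESeq2 called 62 higher and 171 lower, limma 7 and 12 in all at pseudocounts of 1 and 0.1, and edgeR without a filter 8 higher and 25 lower. The count was 1 without the 4-week control and 3 without the 12-week control.

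At 32 weeks the genes of osteopontin, fibronectin and mast cell proteases rose, while those of surfactant protein C and decorin fell. Spp1, which encodes osteopontin (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050, plus strand), rose to 5537 against 310 ± 183 CPM in the controls (SD, n = 5; log2 4.16 ± 0.49 SE, edgeR adjusted p = 0.0176), 24.2 times its matched control. Tpsb2, a mast cell tryptase gene (ENSMUSG00000033825, chromosome 17, 25366305 to 25369098, plus strand), rose to 41.5 against 2.19 ± 0.97 CPM (0.013). Fn1 rose to 1102 against 532 ± 64.4 CPM (0.0439). Sftpc fell to 5940 against 24140 ± 5542 CPM (−2.02 ± 0.36, 0.0439), and Dcn, which encodes the matrix proteoglycan decorin (ENSMUSG00000019929, chromosome 10, 97479609 to 97518143, plus strand), fell to 207 against 769 ± 175 CPM (−1.89 ± 0.34, 0.0444).

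The other large rises at 32 weeks were those of the mast cell and basophil protease genes Mcpt4 (log2 4.28 ± 0.69 SE, edgeR adjusted p = 0.0337) and Prss34 (3.15 ± 0.51, 0.0337) and of Gp2, a glycoprotein gene (3.83 ± 0.62, 0.0337). Falls were those of the transcription factor genes Prrx1 (−3.15 ± 0.58, 0.0455) and Meox2 (−2.57 ± 0.47, 0.0455), of Kcne2 (−2.72 ± 0.51, 0.047) and of Adcy8, from 36 fragments in the matched control to 0 (at least 8.78-fold lower). Phlda3 rose to 76.9 CPM, 1.94 times its matched control (0.0294), the 1 p53 target that passed, with 3 higher and 1 lower when adjusted over the list alone. The p53 list was not called (median 0.12, camera adjusted p = 0.413), and its median was −0.06 with total count scaling. Cdkn1a was at 1.21 times its matched control (0.36 ± 0.23, 0.496).

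Of 16 alveolar type 2 markers 14 lay lower at 32 weeks (median log2 −0.86), and 2 fell, Sftpc and the transcription factor gene Etv5 (−1.38 ± 0.25 SE, edgeR adjusted p = 0.0455), 13 when adjusted over the list alone (camera adjusted p = 4.12e-09; 0.721 with an estimated correlation). All 13 fibroblast markers lay lower (−1.13), of which Dcn fell, and 7 when adjusted over the list alone (4.09e-07; 0.721 with an estimated correlation). Matrix genes were called lower (−0.24, 0.00502; 0.721), with Fn1 up and Dcn down over all genes and 2 up and 7 down when adjusted over the list alone. T cell markers (−1.18, 17 of 17 lower, 0.00144; 0.745 with an estimated correlation), cell cycle genes (−0.66, 34 of 35 lower, 9.69e-05; 0.721) and NK cell markers (−0.12, 0.000399; 0.721) were called lower, with 0, 0 and 2 genes adjusted over the list alone. The medians are against the matched control, while camera compares with all 5 controls. For NK cell markers both 32-week pools were low, at mean log2 CPM 4.178 irradiated and 4.316 control, against 5.196 to 5.451 in the other controls. Thymocyte markers were lower in 4 of 4 (−3.05) and not called (0.612), and the matched control had the highest thymocyte level of the 10 pools (mean log2 CPM 4.958). Ciliated (1.00, 11 of 11 higher, 10 when adjusted over the list alone, 1.05e-05; 0.721 with an estimated correlation) and club markers (0.68, 6, 0.000399; 0.721) were called higher, with 0 passing over all genes. So were plasma cell (1.05, 0, 0.00141; 0.721) and neutrophil markers (0.51, 1, 0.00809; 0.721), again with 0 passing over all genes. Plasma cell markers were high in both 32-week pools, at mean log2 CPM 7.44 irradiated and 6.583 control, against 2.865 to 5.304 in the other controls. The senescence list was not called (−0.06, 0.925), as Spp1 rose and Igfbp4, an insulin-like growth factor binding gene, fell (−1.31 ± 0.24, 0.0455), and 4 rose and 5 fell when adjusted over the list alone. Alveolar macrophage markers were not called (0.40, 0.26, 6 higher and 1 lower adjusted over the list alone). Nor were the other 15 lists, among them red cell (1.79, test lower), endothelial (0.32, test lower) and mesothelial markers (0.05, test lower).

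In all 82 genes rose and 37 fell at 32 weeks with edgeR, 36 and 32 with total count scaling, 507 and 304 with DESeq2, and 333 and 39 or 79 and 29 with limma on FPKM at pseudocounts of 1 or 0.1. Total count scaling moved the median log2 fold of all genes from 0.03 to −0.15 and turned the medians of the p53, interferon-stimulated and mesothelial lists negative. Without a filter 256 rose and 97 fell, and the count of 119 became 38, 6 and 292 without the 24-hour, 1-week and 4-week controls. Without the 24-hour and 1-week controls the edgeR adjusted p was 0.0629 and 0.0653 for Spp1, 0.0629 and 0.088 for Phlda3, 0.0629 and 0.0901 for Prss34 and 0.0625 and 0.0901 for Mcpt4, with a range over their alternatives of 1.81e-05 to 0.0901. Without the 24-hour, 1-week and 12-week controls it was 0.0629, 0.103 and 0.0682 for Sftpc (range over its alternatives 1.28e-11 to 0.103), and without the 1-week and 12-week controls 0.0903 and 0.0592 for Gp2 (4.43e-06 to 0.0903). Without the 24-hour, 1-week, 12-week and 32-week controls it was 0.0713, 0.101, 0.0621 and 0.0567 for Dcn and 0.0821, 0.0901, 0.0606 and 0.0538 for Fn1. In the same order it was 0.0713, 0.088, 0.0592 and 0.0542 for Etv5 and 0.0713, 0.0989, 0.0592 and 0.0617 for Igfbp4. For the transcription factors it was 0.0809, 0.0989, 0.0592 and 0.0617 for Prrx1 and 0.081, 0.0989, 0.0592 and 0.0585 for Meox2. The others had 0.0713, 0.0989, 0.0576 and 0.0602 for Kcne2 and 0.0802, 0.0901, 0.0592 and 0.0624 for Adcy8, with a range over their alternatives of 8.41e-09 to 0.292. Tpsb2 passed in all 12 alternatives that tested it, with an adjusted p of at most 0.0459.

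**Figure D3:**
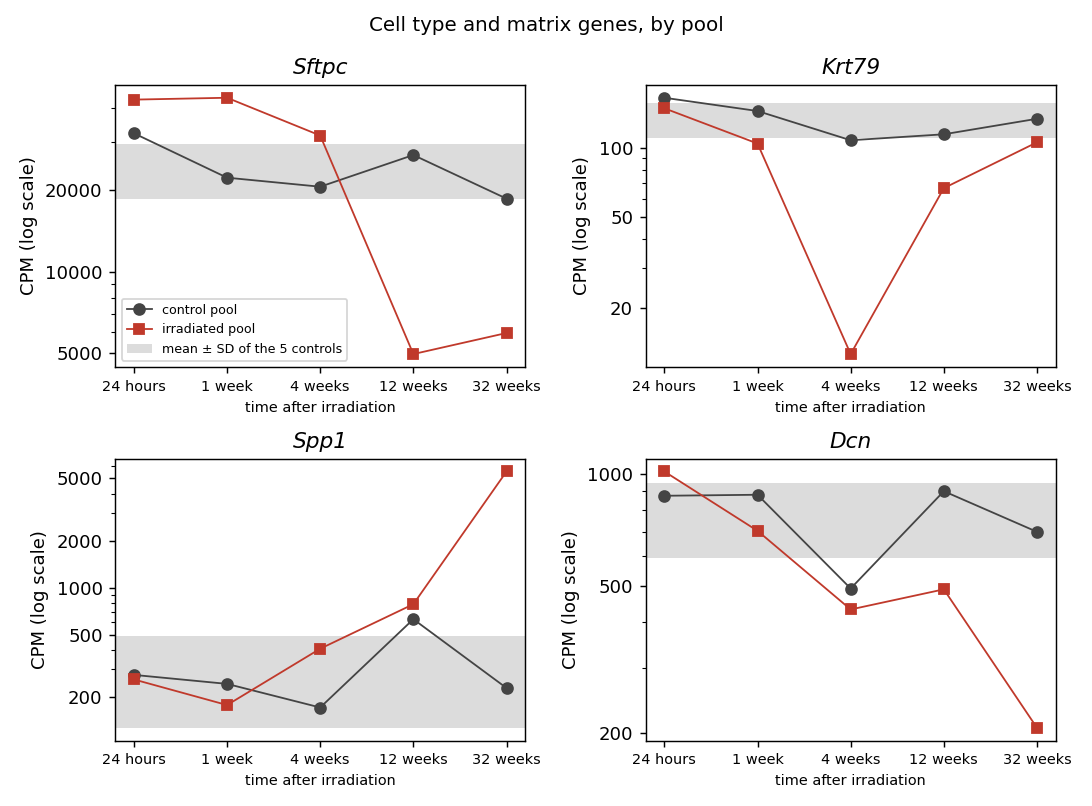
Abundance in CPM (log scale) of Sftpc, Krt79, Spp1 and Dcn in each control pool (circles) and irradiated pool (squares) against time after irradiation, with the mean ± SD of the 5 controls shaded. Irradiated Krt79 is at 12.6 at 4 weeks, irradiated Sftpc at 4967 at 12 weeks, and irradiated Spp1 at 5537 and Dcn at 207 at 32 weeks.

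**Figure D4:**
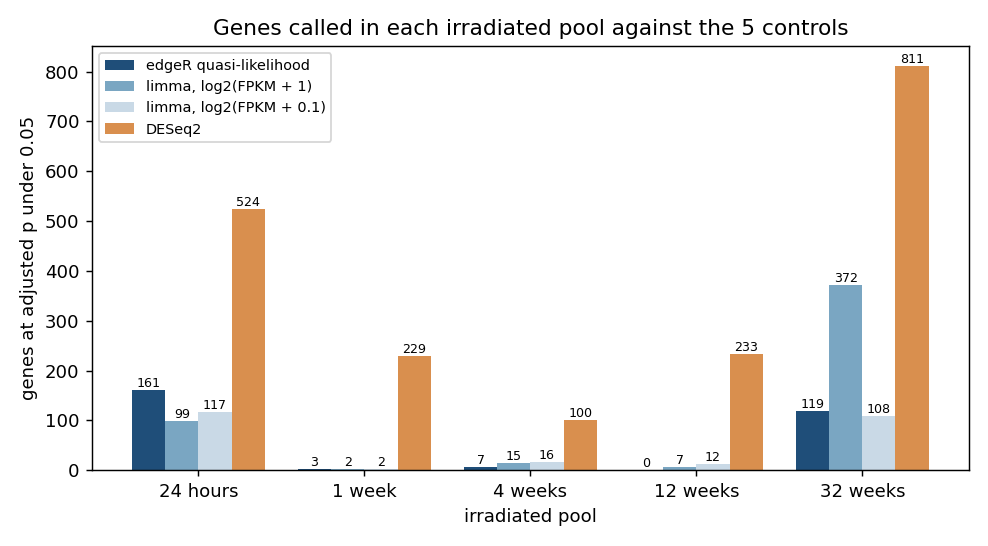
Number of genes at an adjusted p under 0.05 (bars, axis from 0) in each irradiated pool against the 5 controls, by edgeR, limma on log2 FPKM with pseudocounts of 1 and 0.1, and DESeq2. With edgeR the counts are 161, 3, 7, 0 and 119 in time order, and DESeq2 gives the most at every time. The 5 controls span all times, so these counts do not tell irradiation apart from a difference in age.

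The change of the irradiation effect with time asked which genes differ between the early and the late lung. The difference between irradiated and control pools in Cdkn1a changed by −0.29 ± 0.04 per doubling of days (log2, SE; edgeR adjusted p = 0.679) and did not pass. The other genes with the smallest p were all at adjusted p = 0.679. They were Errfi1 (−0.34 ± 0.05), Gas6 (−0.22 ± 0.03), Syn3 (−0.25 ± 0.04), Enpp3 (−0.51 ± 0.09), Ifitm3 (−0.21 ± 0.04), mt-Nd2 (−0.19 ± 0.03) and mt-Nd6 (−0.23 ± 0.04), Cdh2, a cadherin gene (1.18 ± 0.20), and the chemokine receptor gene Cxcr6 (0.26 ± 0.05). edgeR called 0 genes with 1095 at an unadjusted p under 0.05, DESeq2 27 higher and 33 lower, and limma 0 with either pseudocount. camera called 6 lists higher and 9 lower, and 0 held with an estimated correlation. Lower with time were p53 targets (camera adjusted p = 2.46e-08; 0.213 with an estimated correlation, 5 genes adjusted over the list alone), interferon-stimulated genes (3e-08; 0.491) and alveolar type 2 markers (2.46e-08; 0.491). Lower too were senescence (4.86e-05; 0.213), immediate early (1.53e-05; 0.213, 4 genes adjusted over the list alone), circadian (0.00311; 0.286), cytokine (0.00602; 0.491), matrix (0.00405; 0.491) and fibroblast genes (0.000295; 0.491). Higher were cell cycle genes (5.75e-11; 0.491 with an estimated correlation), B cell (2.46e-08; 0.491), DNA damage (0.00432; 0.491), ciliated (0.000178; 0.491), cardiac (0.029; 0.591) and red cell genes (0.00602; 0.528). Differences between single times, as in Krt79, Spp1 or Sftpc, were not tested otherwise.

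In the controls alone, no gene passed for a change with time, and no list was called with an estimated correlation or with fry. Cdh2 fell by 0.92 ± 0.14 per doubling of days (log2, SE; edgeR adjusted p = 0.252) without passing. The next by p were Nat10 (0.21 ± 0.04, 0.464), Lrrn4 (−0.23 ± 0.04), Ighg2b (0.74 ± 0.15), Xist (0.20 ± 0.04), Msln (−0.17 ± 0.04), Nwd1 (0.86 ± 0.18), Malat1 (0.21 ± 0.04, 0.577), Sparc (−0.14 ± 0.03, 0.697) and Pi16 (−0.16 ± 0.04, 0.75). edgeR called 0 genes with 673 at an unadjusted p under 0.05, DESeq2 20 higher and 6 lower, and limma 0 with either pseudocount. camera called 8 lists higher and 9 lower, 0 with an estimated correlation, among them plasma cell markers higher (1.22e-06; 0.378 with an estimated correlation, 5 genes adjusted over the list alone), and mesothelial (1.8e-06; 0.298, 4 genes adjusted over the list alone), matrix (1.42e-05; 0.378) and alveolar type 2 genes lower (0.00395; 0.615).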

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

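Of the tests given here, those of mature T cell genes, of T cell markers at 24 hours, of ribosomal protein genes at 4 weeks and of the epithelial lists at 12 and 32 weeks were chosen only after the result was seen, as were the requirements on spread for the ribosomal protein genes at 12 weeks and for the epithelial lists. The counts of 0 genes were known when the other splits of the pools were drawn.

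Cell cycle genes and T cell markers were low at 24 hours, 1 week and 32 weeks together with thymocyte genes such as Rag1, and a candidate cause is thymus tissue carried along with the lung. At 24 hours the values argued against this as the whole cause of the cell cycle difference. The 1-week control had the lowest thymocyte level of the controls (mean log2 CPM 0.21, against −1.97 in the 24-hour irradiated pool). Yet its cell cycle genes lay 2.02 log2 units (median) above those of that pool (SD between controls 0.25). For T cell markers the difference, 1.42 (0.64), was only just beyond the spread. That control still held 66 fragments of Rag1, against 0 in the irradiated pool, so thymus tissue is not excluded for either list at 24 hours. Over the 5 times thymus tissue stays open for the T cell markers, since 7 genes of mature T cells, 1 of which is also on the T cell list, had a median of −0.17, lower in 3 of 5 pairs, against −0.67 for the T cell markers, although they were called lower at 24 hours (−0.435, adjusted p = 0.00234; 0.331 with an estimated correlation) and 1 week (−0.73, 0.0336; 0.327). At 32 weeks it stays open for both lists, with 4 of 4 thymocyte genes lower (median −3.05) and the highest thymocyte level of any pool in the matched control (4.958), while at 12 weeks thymocyte genes (1.74, 4 of 4 higher), T cell markers (0.25) and cell cycle genes (0.35) were all higher, and at 4 weeks cell cycle genes were higher (0.23) with thymocyte genes lower (−1.08). Loss of dividing cells and lymphocytes after irradiation also stays open and was not tested separately.

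Of 81 ribosomal protein genes 73 were lower in 5 of 5 pairs (median log2 −0.47), with mean levels of 7.16 to 7.65 log2 CPM in irradiated and 7.73 to 8.10 in control pools. Loss of short transcripts was tested with other genes matched on expression and on the length of the longest annotated transcript. That length had a median of 1106 bases for ribosomal protein genes. The matched genes, found for 80 of the 81, had a median of −0.07, with quartiles of −0.12 and 0.02, and so did not share the fall. The longest annotated transcript can be longer than the expressed one, so loss of short transcripts is not excluded. Fewer lymphocytes as the whole cause cannot be told apart from an effect of irradiation: at 12 weeks, when T cell and B cell medians were 0.25 and 0.14, ribosomal protein genes were at −0.35, which lies beyond the SD of 0.23 between controls but within the largest difference between 2 controls, 0.41. At 4 weeks they were at −0.64, beyond that largest difference, with B cell markers at 0.16, mature T cell genes at 0.47 and T cell markers at −0.40, and their difference from the T cell markers (−0.24) is within the SD of 0.70 of that difference between controls. Reads shared with pseudogenes may add to the pattern and were not tested.

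Alveolar type 2 markers lay low at 12 and 32 weeks, and fewer epithelial cells of every type in the suspension could account for that. At 32 weeks the values went against this only just beyond the spread: ciliated markers were at 1.00 (SD between controls 0.75), club markers at 0.67 (0.65) and type 1 markers at −0.05 (0.45), against −0.86 for type 2. Mean ciliated levels (log2 CPM) ran from 4.93 to 6.089 in controls, with 6.827 in the irradiated pool. Club levels ran from 6.951 to 7.886, with 8.511 in that pool. With 1 pair of pools and such differences between controls, the explanation is not excluded at 32 weeks. At 12 weeks it cannot be told apart, since the 3 other lists were low too (highest median −0.42) and type 2 markers were at −1.54. Fewer type 2 cells of an unchanged profile cannot be told apart from a changed profile either, since the spread of the members' log2 folds at 32 weeks was 1.36 times the widest of 10 control pairs (0.72 against 0.53) and the test has 1 irradiated pool. A change in type 2 cells after irradiation remains among the open explanations.

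Chance cannot be excluded for the lists called over the 5 times. With 15 lists called, 23 of 100 splits had as many and the highest other 20, and of 13 splits that part all 5 pairs, as the real one does, 4 had as many. For genes the splits decide nothing, since 0 were called and any split has at least 0. Over the 5 times that holds for all 100 splits drawn (highest other 1), and for the change with time for all 96 that could be fitted (highest other 2).

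Among 138 groups of 5 pools, 11 values lay apart from the rest of their group, where chance marks about 1 in 20 groups. Mitochondrial transcripts took 1.72% in the 24-hour irradiated pool and 1.15% to 1.28% in the other irradiated pools. Cytokine genes were at a mean of 5.411 log2 CPM in the same pool, against 4.829 to 4.991. The sex-linked gene Xist was at 5.383 log2 CPM there, against 5.979 to 6.218. NK cell markers were at 4.316 in the 32-week control, against 5.196 to 5.451. Mast cell markers were at 1.328 in the 4-week control, against 1.696 to 1.824. Lipid-associated macrophage genes were at 9.815 in the 32-week irradiated pool, against 8.616 to 8.923. Alox15 was at 6.66 log2 CPM in the 12-week control, against 5.95 to 6.02. In the 1-week control Rpl37a was at 8.32 (others 8.77 to 8.88), Tmsb10 at 7.28 (7.58 to 7.68) and Rpl37 at 7.10 (7.44 to 7.57), and in the 1-week irradiated pool Rpl37 was at 6.46 (6.89 to 7.01). By a test of the change of effect with log2 days, fry's adjusted p was 0.0243 for senescence genes and 0.0118 for circadian clock genes, both lower with time, while camera with an estimated correlation gave 0.213 and 0.286. Members of the circadian list went opposite ways, some lower and some higher in the irradiated pools after 24 hours. The direction of that list thus does not describe every member, and the cause was not tested.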

How the results depend on the processing

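Unscaled counts, each control against the other 4, and camera at single times were alternatives chosen only after the data were seen, and all others were fixed before. Counts of genes moved with the tool, with the filter and with the control left out, and the cause was not tested. DESeq2 called 258 genes over the 5 times (edgeR 0), 524 at 24 hours (161), 229 at 1 week (3), 100 at 4 weeks (7), 233 at 12 weeks (0), 811 at 32 weeks (119), 60 for the change with time (0) and 26 in the controls (0), of which 159 at 24 hours and 115 at 32 weeks were edgeR calls. DESeq2 also made more false calls on simulated data than edgeR. Without a filter, with 27972 genes tested, the counts were 1 over the 5 times, 249, 20, 29, 33 and 353 at the single times, and 1 for the change with time. The stricter filter, with 11924 genes, gave 11 at 1 week, 1 at 12 weeks and 188 at 32 weeks. limma on log2(FPKM + 1) gave 99 at 24 hours (80 of them edgeR calls), 15 at 4 weeks, 7 at 12 weeks and 372 at 32 weeks (97 of them edgeR calls), and on log2(FPKM + 0.1) 16 at 4 weeks and 12 at 12 weeks. Total count scaling gave 0 at 1 week and 68 at 32 weeks, 66 of them edgeR calls. Leaving out 1 control gave 61 to 162 genes at 24 hours, 0 to 8 at 1 week, 4 to 10 at 4 weeks, 0 to 3 at 12 weeks and 6 to 292 at 32 weeks. Leaving out 1 time gave 0 genes over the 5 times and 0 for the change with time. The lists were called less often with an estimated correlation (0 over the 5 times, 4 at 24 hours and 0 at every later time, and 0 at 24 hours too when adjusted over the lists of all 5 times) and with fry (0 over the 5 times, then 7, 1, 2, 0 and 0), while unscaled counts gave 15 lists over the 5 times, and 11 to 19 were called with 1 time left out. Without the time block 11 lists and 0 genes were called over the 5 times, Col3a1 turned to 0.018, and no other call changed beyond the lists. Col3a1 also turned on log2(FPKM + 1) (0.104), on log2(FPKM + 0.1) (0.105) and without the 32-week pools. With 1 time left out it lay between −0.186 and 0.126, and Col1a1, which turned without the 32-week pools, between −0.389 and 0.067 (adjusted p = 0.774 and 0.928 without these pools). Named genes over the 5 times kept their direction and side of the threshold in 349 gene and alternative pairs and passed in 24, all but 1 of the genes only with DESeq2. Of the named genes that passed, 17 of 41 at 24 hours, 0 of 2 at 1 week, 3 of 6 at 4 weeks and 1 of 16 at 32 weeks passed under every alternative that tested them. At 24 hours these included Cdkn1a, Phlda3, Ccng1, Bax, Ifit3, Irf7, Ccl2, Ccl7, Ccnb2 and Ccna2, at 4 weeks they were Krt79, Ear1 and Cpne5, and at 32 weeks Tpsb2. Depth limits genes of few fragments, such as Cdkn2a, which the filter left out.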

Other observations

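The 7 lists given here and their tests were chosen only after the data were seen, and their adjusted p cover these 7 alone, within each comparison unless said otherwise. At 32 weeks 5 of 5 measured mast cell genes lay above the matched control (median log2 2.62), and 4 rose over all genes, as many as when adjusted over the list alone (limma camera adjusted p = 6.77e-07; 0.0446 with an estimated correlation). Adjusted over these lists at all 5 times, the call was lost with an estimated correlation (adjusted p = 0.178). Tpsb2 was at 0.71, 0.69, 0.53, 6.59 and 23.9 times its matched control in time order. At 12 weeks 4 of 5 lay higher (median 0.91), 0 passing over all genes and 4 adjusted over the list alone (0.000155; 0.107 with an estimated correlation). At 1 week 5 of 5 lay lower (median −0.98), 0 passing over all genes and 2 adjusted over the list alone (0.00299; 0.102 with an estimated correlation). Genes of lipid-associated macrophages, among them Spp1, Trem2, Gpnmb and Lpl, had 10 of 10 higher at 32 weeks (median 1.53), 4 rising over all genes and 7 adjusted over the list alone (8.43e-07; 0.187 with an estimated correlation). Cholesterol metabolism genes, such as Sqle, had 10 of 10 higher (median 1.23), 4 rising and 10 adjusted over the list alone (6.29e-08; 0.187 with an estimated correlation).

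Fatty acid synthesis genes, such as Scd1, Fasn and Acaca, lay high early. At 1 week 8 of 8 were higher (median 1.05, 0 passing and 7 adjusted over the list alone, 1.85e-07; 0.101 with an estimated correlation) and at 4 weeks 8 of 8 (0.72, 0 and 4, 0.000118; 0.206). The median was 0.45 at 24 hours and −0.26 at 12 weeks. The 24-hour list was called too, at camera adjusted p = 0.00301 over these lists at all 5 times (0.28 with an estimated correlation). Alveolar type 2 markers, a list that shares Scd1 with this one, had medians of 0.49, 1.17, 0.70, −1.54 and −0.86 in time order. The 32-week median of 0.12 became −0.06 with total count scaling. Ribosomal protein genes had 80 of 81 lower over the 5 times (median −0.47), 0 passing over all genes and 76 adjusted over the list alone (1.27e-44; 0.191 with an estimated correlation), with medians of −0.48, −0.58, −0.64, −0.35 and −0.32 in time order. Mitochondrially encoded genes went from a median of 0.16 at 24 hours to −0.86 at 32 weeks, and their change with log2 days was called (2.11e-08; 0.178 with an estimated correlation, 8 genes lower adjusted over the list alone). From 4 to 32 weeks the irradiated pools stayed level, at mean log2 CPM 8.247, 8.29 and 8.294. The controls rose over these times, at 8.644, 8.796 and 9.199, so the later widening lay in the controls. The mature T cell genes were not called over the 5 times (median −0.17, 0.31).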
